A study of Homo sapiens with 4 samples.

How the data were processed

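MM1.S is an established human multiple myeloma cell line, a model of malignant plasma cells. Per the labels' protocols, untreated cells were fixed with formaldehyde, the chromatin was sheared, and DNA bound by the transcription factor IRF3 was immunoprecipitated and sequenced. The series held 4 samples, which were 2 IRF3 ChIP libraries and 2 input libraries, numbered 1 and 2 in the labels. A peak list was analysed here for each ChIP library, and the input libraries entered only through the peak calls made against them. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical.

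Per the file headers, the authors called narrow peaks with MACS2 for each ChIP library separately against the input library of the same number, with a q-value cutoff of 0.05, an effective genome size of 2.70e+09 bp and all duplicate tags kept at that step. The file headers name MACS2 version 2.1.2, while the submitters' processing notes name version 2.1.1. The submitters' processing notes also name BWA 0.7.15, Picard 2.6.0, SAMtools 1.2, deepTools 3.3.1 and the genome build GRCh38, without stating the role of each. Per the file headers, tags were 74 bp long, and the modelled fragment length was 267 bp in replicate 1 and 251 bp in replicate 2. Any removal of duplicates or of problem regions before peak calling is not given in the sources used here. Copy-rich loci, such as small nuclear RNA genes, can gain signal from such regions.

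The deposited fold enrichment of each peak is a ratio of the ChIP pileup to the local input background at the summit, made by the authors' peak caller. The deposited pileup is a signal, the height of stacked fragments at the summit. The deposited −log10 p and −log10 q of each peak came under column names damaged by a spreadsheet, and they were told apart by the column order of MACS2 and by the values, since the first exceeded the second at each peak and the lowest −log10 q lay at the cutoff. All of these values are the authors' own for each peak and were used here to describe, rank and filter peaks within a list. Fold enrichment depends on antibody recovery and on the input depth, so a different median in 1 library is not a difference in binding.

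Peaks of both replicates that overlapped by at least 1 bp were merged into regions with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. A region with a peak from each replicate was called shared. The strongest peak of each replicate in a region gave its fold enrichment. Regions were ranked by the worse of the 2 ranks that fold enrichment gave within the replicates, and the summit of a region was that of its strongest peak. Chance overlap was measured with 100 shuffles of 1 list within its chromosomes. The shuffles leave uneven mappability out of account.

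Genes were taken from a RefSeq gene table of assembly GRCh38.p14 that gives the span and type of each gene without its strand, exons or transcripts. A start site could therefore not be told from the other end of a gene, and the planned distance to start sites was replaced by the distance to either end of the gene span. This change was made after the files were seen. A gene was called occupied when the summit of a shared region lay within 1 kb of either end. The planned search for 23 sequence motifs needed a genome sequence and was not run, so whether the regions hold IRF binding sequences was not analysed here. Promoter CpG content was not used here for the same reason.

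For 15 gene lists, fixed before the data were examined, the share of occupied members was compared with that of all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists (scipy 1.17.1, statsmodels 0.14.6). Of the 543 list genes, 542 matched the table. The strength of the occupied members was described by the percentile of their region rank among all occupied protein-coding genes, 100 being the strongest. The median percentile of a list was compared with 100000 random sets of as many occupied genes, drawn with replacement, in a two-sided permutation test. That strength test was added after the files were seen. Intervals are exact binomial (Clopper-Pearson) or conditional odds ratio intervals at the 95% level and cover counting error only. Neighbouring genes can share a region and related genes are not independent, so the p-values of lists are likely lower than independent genes would give.

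The rule for named genes and regions, fixed before the data were examined, took the 15 genes at the highest-ranked regions, the 5 highest-ranked regions over 10 kb from a gene end, up to 4 members of each list with the best-ranked regions, 20 genes named in advance whether occupied or not, and the 3 strongest regions of each replicate alone. It gave 86 genes, and a few items that it named are not reported here. Further genes are named in list descriptions and in the closing section, and those were chosen after their values were seen.

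The list test was tested on simulated data for 20037 genes, with 40 genes per list and 50% of other genes occupied. It called 10 of 10 simulated lists at a true share of 90%, 10 of 10 at 10% and 5 of 10 at 75%. None of 40 lists without a difference was called. Occupancy was drawn independently for each gene and lists were drawn at random. The simulation therefore does not show how the test behaves for neighbouring or related genes. The merging of peaks gave 8919 shared regions on a simulated pair of lists, as did bedtools 2.31.1. With 2 replicates of 1 condition, no test of a difference between conditions was possible. Alternatives covered the overlap rule, peak thresholds, distance limits, each replicate alone and the measure of strength. Figures were drawn with matplotlib 3.10.9.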

Results

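The genome-wide binding of IRF3 was profiled by ChIP-seq in untreated MM1.S cells, to locate where this transcription factor sits in myeloma chromatin. IRF3 is known as an activator of type I interferon and antiviral genes downstream of cytosolic nucleic-acid sensors. There were 2 IRF3 ChIP replicates, each with its own input. Peak calling used 38568845 ChIP tags and 58025919 input tags in replicate 1, and 46474586 ChIP tags and 60348415 input tags in replicate 2. The lists held 41880 and 41666 peaks. The median fold enrichment over input, the authors' own value for each peak, was 3.90 in replicate 1 (quartiles 3.01 and 5.39) and 4.30 in replicate 2 (quartiles 3.23 and 6.56). Median peak lengths were 528 and 574 bp, and the peaks covered 27.2 and 30.7 Mb. The lists were not copies of each other, since 2 peaks had the same start and end in both and none of those had the same fold enrichment.

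IRF3 peaks fell largely at the same places in both replicates. Merging gave 32246 shared regions, 8164 regions of replicate 1 alone and 8679 regions of replicate 2 alone. Shared regions took in 80.5% of the peaks of replicate 1 and 79.2% of those of replicate 2. Among the strongest 20% of peaks by fold enrichment the shares were 98.6% and 99.4%, and among the weakest 20% 65.1% and 56.0%. Shuffled peaks gave 808 ± 24 shared regions (SD over 100 shuffles, highest 876), so the observed number was 39.9 times that of chance placement. Summits in shared regions lay a median of 48 bp apart, with 76.9% within 100 bp.

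Shared regions were concentrated at the ends of protein-coding genes, where promoters lie at the start end. A summit lay within 1 kb of a gene end in 28.4% of shared regions (9160 of 32246, exact 95% interval 27.9 to 28.9%), against 2.61% ± 0.0745 (SD) for shuffled regions. A further 53.6% of shared regions lay over 10 kb from any such end, compared with 81.4% of shuffled regions. A class that overlaps with this one, regions inside a gene body away from its ends, held 37.2% of shared regions and 41.2% ± 0.279 (SD) of shuffled regions. The share at gene ends was 59.9% in the strongest 20% of shared regions (95% interval 58.7 to 61.1%), then 33.4%, 21.7% and 15.1%, and 12% in the weakest 20% (11.2 to 12.8%). Of 20037 protein-coding genes, 10026 (50.04%) were occupied. Nearly all of these, 9463 genes (94.4%), had a region at 1 end and not the other. The summit lay a median of 155 bp from the gene end. In the 14343 genes over 10 kb long, 29.0% had a region at the lower-coordinate end, 28.1% at the higher-coordinate end and 2.35% at the midpoint.

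The regions found in a single replicate differed in location. Regions of replicate 1 alone lay at gene ends in 4.32% of cases (95% interval 3.89 to 4.79%) and those of replicate 2 alone in 18.0% (17.1 to 18.8%), an odds ratio of 4.84 (95% interval 4.29 to 5.47, two-sided Fisher's exact p = 1.06e-183). Shared regions lay there more often than either set, with odds ratios of 8.78 (7.87 to 9.82) against replicate 1 alone and 1.81 (1.71 to 1.93, exact p = 3.44e-91) against replicate 2 alone. The regions of each set came from a single library, so these p-values count regions and do not measure spread between replicates. These odds ratios do not match strength. Median fold enrichment was 4.28 and 4.94 in shared regions, against 3.14 in replicate 1 alone and 3.20 in replicate 2 alone. The weakest 2 of the 5 strength classes of shared regions had 15.1% and 12% at gene ends, below the 18.0% of replicate 2 alone. The strongest regions of replicate 1 alone were inside CNTN5 on chromosome 11 (100329284 to 100329763, fold enrichment 9.31), inside CLIC5 on chromosome 6 (45923898 to 45924507, 9.18) and 925 kb from ARAP2 on chromosome 4 (35079905 to 35080338, 8.88). Those of replicate 2 alone were at CHAC1 on chromosome 15 (40952558 to 40953961, fold enrichment 19.2), 112 bp from a gene end, 182 kb from MDGA2 on chromosome 14 (12.8) and 3.67 kb from ARHGAP23 on chromosome 17 (11.9).

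**Figure D1:**
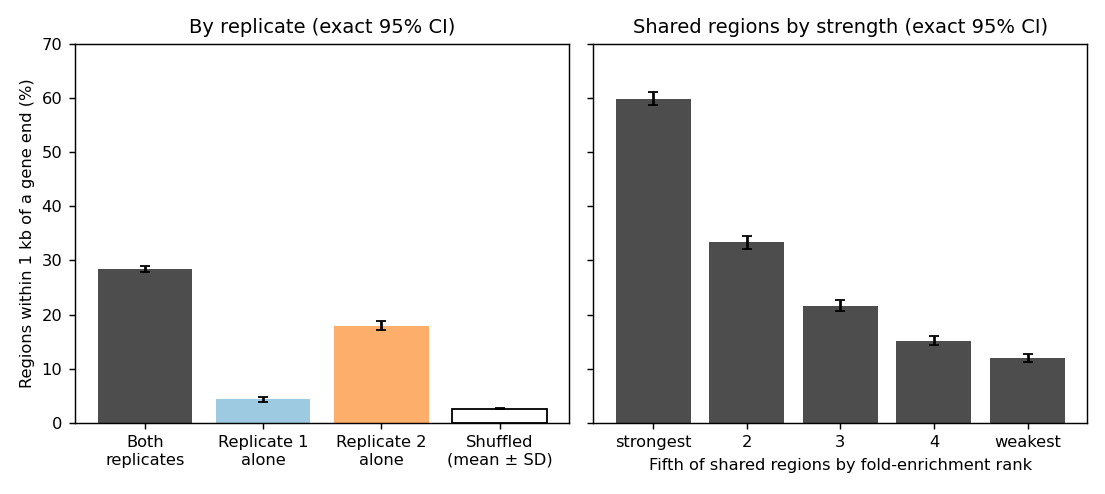
Percentage of regions with a summit within 1 kb of an end of a protein-coding gene, on the vertical axes. The left bars show regions by replicate and shuffled regions, at 28.4, 4.32, 18.0 and 2.61%, and the right bars show shared regions by strength, falling from 59.9% in the strongest 20% to 12% in the weakest; error bars are exact 95% intervals, or the SD over 100 shuffles for the shuffled bar.

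Peak strength was related between the replicates. Across the 32246 shared regions, which are not independent replicates, the rank correlation of fold enrichment was 0.67 (Spearman) and the correlation of log2 fold enrichment was 0.73 (Pearson). Of the 3224 strongest regions in each replicate, 1882 were the same (58.4%, against 10.0% by chance). Fold enrichment was higher in replicate 2 in 68.2% of shared regions, with a median log2 ratio of 0.25.

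**Figure D2:**
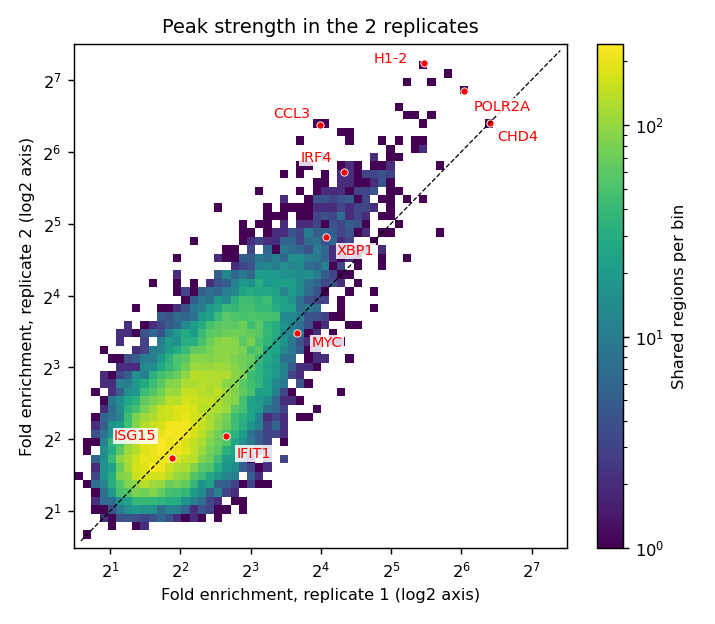
Fold enrichment over input of the 32246 shared regions in replicate 1 (horizontal, log2 axis) and replicate 2 (vertical, log2 axis), coloured by the number of regions per bin, with the regions at 9 named genes as red points and a dashed line of equal values. POLR2A (66.0 and 115), CHD4 and H1-2 lie at the upper end, while ISG15 (3.68 and 3.34) and IFIT1 (6.25 and 4.13) lie in the dense lower part.

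The 15 genes at the highest-ranked regions included genes of transcription, chromatin, RNA processing and translation. No member of the interferon-stimulated list was among them. That list held 50 of the 10026 occupied genes, so its absence among 15 carries little weight. The region at POLR2A, the largest subunit of RNA polymerase II, ranked first among protein-coding genes (chromosome 17, 7483070 to 7485214, with its summit 134 bp from a gene end), with fold enrichments of 66.0 in replicate 1 and 115 in replicate 2. CHD4, a chromatin remodeller, had 85.1 and 84.3 (chromosome 12, 6605463 to 6608948). Histone genes took 4 of the 15 places. These were the linker histone genes H1-2 (44.3 and 151), H1-10 (36.6 and 90.7) and H1-4 (33.4 and 98.1), and H3-3B, which encodes the replication-independent histone H3.3 (35.5 and 73.3). Genes of RNA and protein production followed, namely the splicing factor SRSF7 (32.2 and 63.1), the translation factors EIF1 (32.0 and 64.2) and EEF1A1 (30.6 and 54.6), and the prolyl isomerase PPIA (31.4 and 53.8). The others were the RNA-binding regulator ARID5A (34.6 and 59.7), the antiproliferative gene BTG2 (31.0 and 52.4), the small GTPase gene RHOB (28.8 and 73.4), the stress gene GADD45B (33.0 and 51.2) and RCC1, the exchange factor of Ran (29.6 and 50.9).

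Far from protein-coding genes, 4 of the 5 highest-ranked shared regions over 10 kb from a gene end covered non-coding RNA genes. Of these, 2 covered the genes of the U3 small nucleolar RNA. These were SNORD3A (chromosome 17, 19187833 to 19188444, fold enrichment 46.2 and 127) and SNORD3B-1 (chromosome 17, 19061908 to 19062748, 36.8 and 121). A region of 11.9 kb covered MALAT1, a nuclear long non-coding RNA (chromosome 11, 65496422 to 65508310, 44.5 and 86.6). A small nuclear RNA gene on chromosome 1 lay in another (146376125 to 146378244, 39.5 and 72.4). SNORD3A and SNORD3B-1 belong to a family of near-identical copies, so reads at them may be placed on the wrong copy.

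Interferon-stimulated genes, the class of antiviral effectors that IRF factors are known to activate, were occupied more often than other genes. The other genes are all remaining protein-coding genes, active or not. Among the 10 lists occupied more often, this one had the lowest odds ratio within 1 kb, close to the 3.38 of plasma cell and myeloma genes. That order was not stable. Plasma cell and myeloma genes had the lower odds ratio within 500 bp (2.35 against 3.20) and with either replicate left out. In the remaining settings the interferon-stimulated list stayed lowest of these lists. Of 65 members, 50 were occupied (76.9%, 95% interval 64.8 to 86.5%), against 49.9% of other protein-coding genes (odds ratio 3.34, 95% interval 1.84 to 6.41, adjusted p = 3.81e-05, Fisher's exact test). The best-ranked were TRIM25, a ubiquitin ligase of RIG-I signalling (fold enrichment 11.1 in replicate 1 and 35.6 in replicate 2), ZNFX1 (13.3 and 16.2), the aminopeptidase LAP3 (9.31 and 19.2) and IRF7 (8.69 and 15.5). Classic members had lower values, with MX1 at 6.50 and 7.85, IFIT1 at 6.25 and 4.13 and ISG15 at 3.68 and 3.34. The occupied members had a median strength percentile of 43.5 (quartiles 17.1 and 56.8), which did not differ detectably from random occupied genes (adjusted permutation p = 0.470). When both replicates had to reach a fold enrichment of 5, 26 of 65 members (40%) were occupied against 28.6% of other genes, and the difference was no longer past the threshold (odds ratio 1.67, 95% interval 0.974 to 2.81, adjusted exact p = 0.0664).

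The genes not occupied included several textbook IRF3 targets. IFIT2 had a peak in replicate 2 alone (fold enrichment 3.27), as did OASL (5.15). IFIT3 had 2 shared regions inside its annotated span and none at its ends. The gene table gave no transcripts, so whether these lay at a start site inside the span could not be told. The IFITM1, IFITM2, IFITM3 and IFI27 genes had no peak at an end in either replicate. In the list of interferon and chemokine genes, 6 of 28 members were occupied (21.4%, 95% interval 8.30 to 41.0%, odds ratio 0.27, adjusted exact p = 0.00286), which was less often than other genes. IFNB1, which encodes interferon beta, had its nearest shared region 15.7 kb away. CXCL10 had a peak in replicate 1 alone (fold enrichment 2.74), with the nearest shared region 4.68 kb away. The occupied members included the macrophage inflammatory protein genes CCL3 (15.8 and 82.5) and CCL4 (4.90 and 10.8), as well as CCL5 (6.19 and 16.5) and IL12A (6.19 and 7.19). With a limit of 5 kb in place of 1 kb, 53.6% of this list was occupied and it did not differ detectably from other genes (adjusted exact p = 0.619).

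**Figure D3:**
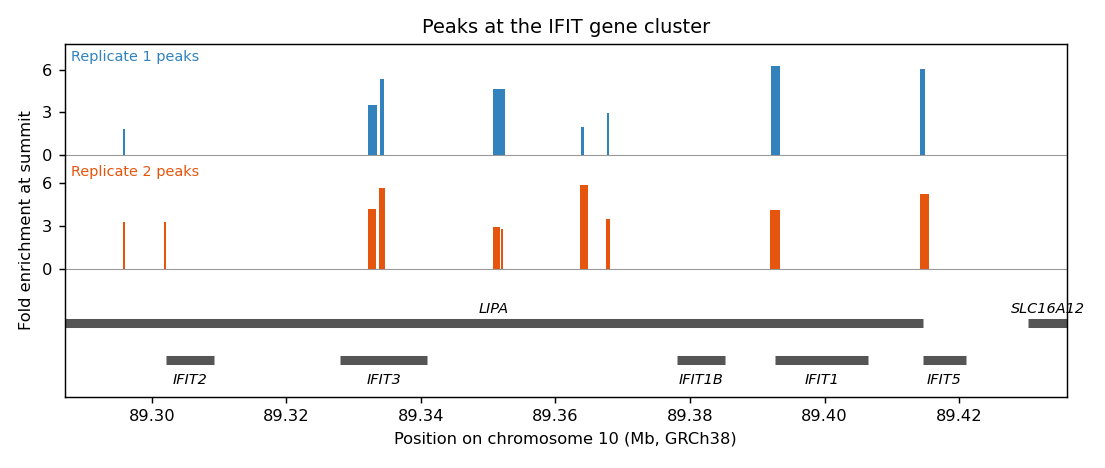
Map of peaks at the IFIT gene cluster on chromosome 10 (89287046 to 89435997, GRCh38), with position in Mb on the horizontal axis, the fold enrichment of each peak as bar height for replicate 1 (blue) and replicate 2 (orange), and gene spans in grey. Both replicates had a peak at the lower-coordinate end of IFIT1 (6.25 and 4.13) and 2 within IFIT3, while at the end of IFIT2 only replicate 2 had a peak (3.27). Both also had a peak at the lower-coordinate end of IFIT5 (6.02 and 5.29), where the span of LIPA ends as well.

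Genes of nucleic-acid sensing, the pathway upstream of IRF3, were occupied in 27 of 34 cases (79.4%, odds ratio 3.86, 95% interval 1.64 to 10.5, adjusted exact p = 0.00122). The odds ratio was 2.56 within 500 bp (23 of 34, adjusted exact p = 0.0125) and 2.50 at a fold enrichment of at least 5 (17 of 34, adjusted exact p = 0.0178). The helicase gene DDX3X had fold enrichments of 26.1 and 37.8, the kinase gene IRAK1 11.7 and 15, and UNC93B1, a chaperone of endosomal Toll-like receptors, 9.04 and 12.7. The IRF3 kinase gene TBK1 had 5.28 and 9.48. STING1, the adaptor of cytosolic DNA sensing, was not occupied and its nearest shared region was 29.3 kb away. Of the 9 IRF family genes, 6 were occupied (66.7%, 95% interval 29.9 to 92.5%), which did not differ detectably from other genes (adjusted p = 0.544, Fisher's exact test). Their median strength percentile was 86.9 (adjusted permutation p = 0.0399). With the limit of 5 kb all 9 were occupied and the list passed the threshold (adjusted p = 0.0164, Fisher's exact test). IRF4, a survival factor of myeloma cells, had the strongest region of the family (chromosome 6, 390441 to 395077, fold enrichment 20.1 and 52.4), followed by IRF1 (14.8 and 26.6), IRF7 and IRF2 (9.48 and 12.3). The IRF3 gene itself had 4.57 and 6.69.

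Plasma cell and myeloma genes were occupied often and strongly. Of 35 members, 27 were occupied (77.1%, odds ratio 3.38, 95% interval 1.49 to 8.60, adjusted exact p = 0.00254), and their median strength percentile was 86.0 (quartiles 42.1 and 95.2, adjusted permutation p = 1.5e-04, from the smallest p the permutations can give). The odds ratio was 2.35 within 500 bp (23 of 35, adjusted exact p = 0.0207) and 11.5 within 5 kb (33 of 35, adjusted exact p = 1.45e-05). Besides IRF4, the kinase gene PIM2 had 24.7 and 40.6, the myeloma tumour suppressor TENT5C 26.0 and 27.6, and XBP1, the secretory regulator of plasma cells, 16.9 and 28.1. The oncogenes MYC (12.7 and 11.2) and MAF (13.9 and 17.6) were occupied as well. PRDM1, which encodes the plasma cell regulator BLIMP1, had 4.07 and 6.09 at its end. In contrast, 11 of 25 B cell genes were occupied (44.0%, adjusted exact p = 0.557), with a median strength percentile of 15.2 (adjusted permutation p = 0.0214), and at a fold enrichment of at least 5 there were 3 (odds ratio 0.34, adjusted exact p = 0.0882). BANK1 had the best-ranked region (7.31 and 8.29), ahead of CR2, BLNK and CD83, and MS4A1 had no peak at an end in either replicate. Occupancy differed between the plasma cell and B cell lists (odds ratio 4.18, 95% interval 1.23 to 15.3, adjusted exact p = 0.0279 over 8 pairs of lists chosen after the data were seen).

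Within 1 kb, antigen presentation genes were occupied more often in class I than in class II. In MHC class I, 20 of 21 genes were occupied (95.2%, odds ratio 20.01, 95% interval 3.20 to 829, adjusted exact p = 4.46e-05), with HLA-G the exception. With regions nearer to an end of another gene left out, 16 were occupied (76.2%, odds ratio 4.31, adjusted exact p = 0.00411), and at a fold enrichment of at least 5 there were 13 (odds ratio 4.07, adjusted exact p = 0.00438). Within 500 bp there were 17 (odds ratio 5.20, adjusted exact p = 0.00261). The strongest were CALR (21.9 and 57.5), B2M (25.9 and 39.6), HLA-E (15.7 and 22.8) and PDIA3 (9.27 and 17.2). The list is thus not of HLA genes alone, and CALR is also on the unfolded protein response list. In MHC class II, 5 of 13 genes were occupied (38.5%, adjusted exact p = 0.489). Within 5 kb this turned to 9 of 13 (69.2%, odds ratio 1.57, adjusted exact p = 0.619), above the 58.9% of other genes, so no direction is given for this list. CD74, the invariant chain, had 18.3 and 25.1, while HLA-DRA had 4.13 and 6.85 and HLA-DQB1 3.51 and 2.55. The region at CIITA (6.14 and 5.32) was nearer to an end of DEXI. The difference between the 2 classes within 1 kb had an odds ratio of 27.9 (95% interval 2.79 to 1487, adjusted exact p = 0.00141, over the same 8 pairs). Within 5 kb, where 20 of 21 class I and 9 of 13 class II genes were occupied, the classes were not compared. Reads at classical HLA genes, which vary and resemble each other, may be misplaced between members.

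Genes of the unfolded protein response, which plasma cells use to sustain secretion, were occupied in 31 of 33 cases (93.9%, odds ratio 15.5, 95% interval 3.95 to 134, adjusted exact p = 3.85e-07), with a median strength percentile of 77.6 (adjusted permutation p = 0.0032). HERPUD1, an endoplasmic reticulum degradation factor, had 27.0 and 48.3, the transcription factor genes ATF4 and DDIT3 had 21.9 and 50.9 and 16.3 and 48.8, and ATF3 and PDIA6 were not occupied. The region at DDIT3 was nearer to an end of LOC128125814. Without regions nearer to another gene the odds ratio of this list was 5.01 (26 of 33, adjusted exact p = 6.05e-05), and without replicate 2 it was 9.49 (30 of 33, adjusted exact p = 4.41e-06). At a fold enrichment of at least 5 it was 6.68 (24 of 33, adjusted exact p = 7.06e-07). Apoptosis genes were occupied in 27 of 32 cases (84.4%, odds ratio 5.40, adjusted exact p = 2.10e-04), with an odds ratio of 12.2 without replicate 1 (30 of 32, adjusted exact p = 6.37e-06) and 2.84 at a fold enrichment of at least 5 (17 of 32, adjusted exact p = 0.00824). Among them were CYCS (19.6 and 35.4), MCL1, a survival gene of myeloma (15.1 and 28.8), and BCL2L11, which encodes BIM (13.3 and 17.9). NF-κB pathway genes were occupied in 25 of 30 cases (83.3%, odds ratio 5.002, adjusted exact p = 5.36e-04; within 500 bp 21 of 30, odds ratio 2.86, adjusted exact p = 0.0125), led by NFKBIA (14.6 and 23), NFKB2 (12 and 21.1), BIRC3 (12.2 and 14) and MAP3K14 (9.30 and 14).

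Genes active in any dividing cell had high occupancy. All 75 ribosomal protein genes were occupied (95% interval 95.2 to 100%, adjusted exact p = 6.92e-22), with a median strength percentile of 94.9 (adjusted permutation p = 1.5e-04). Those ranked highest were RPLP1 (30.4 and 41.9), RPL3 (21.3 and 75.5), RPS4X (20.3 and 39.2) and RPLP0 (20.1 and 57.5). Proteasome genes were occupied in 31 of 32 cases (96.9%, odds ratio 31.0, adjusted exact p = 5.64e-08), among them PSMD8 (11.7 and 20.4) and PSMA4 (12.7 and 16). Cell cycle genes were occupied in 45 of 50 cases (90.0%, odds ratio 9.02, adjusted exact p = 2.02e-08), led by GMNN (13.5 and 23.9), RRM2 (11.4 and 38.3), CDC25C (11.1 and 18.6) and RBL1 (12.7 and 16.8). Without regions nearer to another gene, the odds ratios were 7.29 for the proteasome (27 of 32, adjusted exact p = 5.63e-06), 4.79 for the cell cycle (39 of 50, adjusted exact p = 2.13e-06) and 18.99 for ribosomal protein genes (70 of 75, adjusted exact p = 1.74e-19). At a fold enrichment of at least 5 they were 13.5 for the proteasome (27 of 32, adjusted exact p = 6.05e-10) and 3.19 for the cell cycle (28 of 50, adjusted exact p = 1.37e-04), and all 75 ribosomal protein genes were occupied. Within 500 bp the cell cycle had 5.59 (41 of 50), the proteasome 18.4 (30 of 32) and ribosomal protein genes 29.6 (72 of 75), and within 5 kb the cell cycle had 34.3 (49 of 50). Interferon-stimulated genes were occupied less often than ribosomal protein genes (adjusted exact p = 1.52e-05) and proteasome genes (adjusted exact p = 0.0279). No difference was detected from cell cycle genes (adjusted exact p = 0.0961) or unfolded protein response genes (odds ratio 0.22, adjusted exact p = 0.0631). The same held against plasma cell and myeloma genes (odds ratio 0.99, 95% interval 0.320 to 2.87). Of 74 genes restricted to other tissues, 4 were occupied (5.41%, 95% interval 1.49 to 13.3%, odds ratio 0.0567, adjusted exact p = 4.38e-16). These were KRT10 (5.24 and 10.8), SFTPC (3.51 and 5.06), CD3E (2.50 and 2.63) and COL1A1 (2.41 and 3.47), and the region at SFTPC was nearer to an end of BMP1. The count was 1 of 74 within 500 bp (adjusted exact p = 3.20e-17), 10 of 74 within 5 kb (13.5%, adjusted exact p = 8.76e-15) and 7 of 74 without replicate 1 (9.46%, adjusted exact p = 9.39e-16), as well as 1 at a fold enrichment of at least 5 and 2 at a −log10 q of at least 5, and the list stayed below other genes in each. Of the 15 lists, 10 were occupied more often than other genes, 2 less often, and 3 did not pass the threshold.

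**Figure D4:**
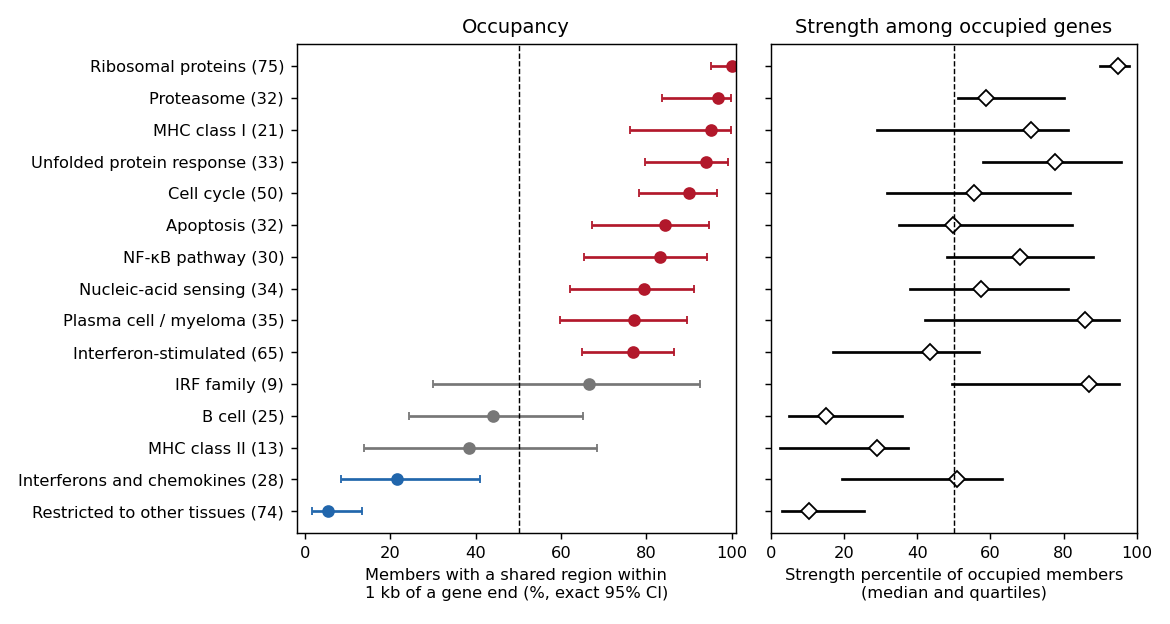
Left, percentage of each list's members with a shared region within 1 kb of a gene end, with exact 95% intervals and the 50.04% of all protein-coding genes as a dashed line; red and blue mark lists occupied more and less often past an adjusted p of 0.05, grey those not past it, and member numbers stand in brackets. Right, median and quartiles of the strength percentile of occupied members, where ribosomal protein genes (94.9) and plasma cell genes (86.0) lie high and interferon-stimulated genes lie at 43.5.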

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

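The replacement of start sites by gene ends, the strength percentiles, the separate gene ends and the removal of regions nearer to another gene were chosen after seeing the data. The number of shared regions stayed within 1.5 times of 32246 under reciprocal overlap, summit distance and the q-value limit, and it was 9678 with a fold enrichment of at least 5 and 3026 from the 5000 strongest peaks of each replicate, both of which admit fewer peaks. The share at gene ends was 25.3% within 500 bp, 38.6% within 5 kb, 30.3% by any base of the region, 50.4% at a fold enrichment of at least 5, 31.3% at a −log10 q of at least 5, and 23.9 to 26.4% with a replicate left out. The rank correlation between replicates was 0.77 by −log10 q and 0.85 by pileup, against 0.67 by fold enrichment. Occupancy of interferon-stimulated genes kept its direction throughout and its side of the threshold except at a fold enrichment of at least 5 (40%, adjusted exact p = 0.0664), where fewer regions remained; whether that alone ended the call was not tested. The interferon and chemokine list and the IRF family changed their calls within 5 kb (53.6%, adjusted exact p = 0.619, and 100%, adjusted exact p = 0.0164). The other lists kept their calls in every setting, though odds ratios moved by more than 1.5 times, as from 5.40 to 12.2 for apoptosis without replicate 1. Of the 86 named genes, 11 lost or gained occupancy at a fold enrichment of at least 5, 8 within 500 bp, 2 within 5 kb, 3 at a −log10 q of at least 5, 2 without replicate 1, 1 without replicate 2, and 4 without regions nearer to another gene (CIITA, DDIT3, PSMC5 and SFTPC). No list changed its call on strength by −log10 q. No paired analysis was possible because the input samples entered only through the peak calls and no test compared them with the ChIP samples. The motif alternatives, the CpG-stratified odds ratio and the most upstream start site were not run. Depth was 38568845 and 46474586 ChIP tags, and of the weakest 20% of peaks only 65.1% and 56.0% lay in shared regions, so an unoccupied gene may hold binding under that limit.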

Other observations

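The gene families, gene types, dense windows, the broad regions with their limit of 5 kb, the tests on small RNA genes and the test of interferon-stimulated against ribosomal protein genes were chosen after the data were seen. Histone genes were occupied in 59 of 87 cases (67.8%, odds ratio 2.11, 95% interval 1.32 to 3.44, adjusted p = 0.0016, Fisher's exact test over 7 families), with a median strength percentile of 96.7. SRSF splicing factor genes were occupied in 11 of 12 cases (adjusted exact p = 0.00739) and initiation factor genes in 47 of 56 (adjusted exact p = 4.34e-07). Zinc finger genes did not differ detectably from other genes (51.1%, adjusted exact p = 0.656). Occupancy was low at olfactory receptor genes (6 of 392), keratin genes (1 of 55, adjusted exact p = 4.97e-15) and homeobox HOX genes (3 of 39, adjusted exact p = 4.33e-08). Among other gene types, regions lay at 35.7% of transfer RNA genes (158 of 443), 25.3% of small nuclear RNA genes (39 of 154), 17.2% of long non-coding RNA genes (3148 of 18303) and 2.26% of pseudogenes. Such a region can lie at a coding gene as well, as the region at H1-10 also covered the long non-coding RNA gene H1-10-AS1. No chance share is given for these gene types.

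Shared regions were spread over 14646 windows of 100 kb, with a median of 2 regions in each. The densest windows held 18 regions each. They lay at CCDC88C on chromosome 14 (91300000 to 91399999) and at IRF1 on chromosome 5 (132400000 to 132499999). A window with the plasma cell surface gene SLAMF7 and its relatives CD48 and LY9 on chromosome 1 held 13.

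Ribosomal protein genes, which are active in any cell, had the highest median strength percentile of the 15 lists, ahead of the IRF family (86.9) and plasma cell genes (86.0). The region ranked highest of all covered the small nuclear RNA gene RNVU1-27 (chromosome 1, 148521935 to 148523985, fold enrichment 54.3 and 136). Occupancy strongest at interferon-stimulated genes was argued against, since their median strength percentile of 43.5 compared with 94.9 for ribosomal protein genes, a difference of -51.5 (permutation p = 1e-05, the smallest the permutations can give), although the test chosen first, against random occupied genes, had not decided it (permutation p = 0.345). A pile-up of reads at multicopy small RNA genes was argued against only as the source of most of the 100 strongest regions. Of these, 15 had such a gene nearest (95% interval 8.65 to 23.5%), and for those 15 a pile-up stays open. It also stays open for the very strongest, where 7 of the top 20 had such a gene nearest (15.4 to 59.2%). A candidate explanation is that highly transcribed chromatin was recovered whatever the antibody bound, and the percentile of 94.9 for ribosomal protein genes went in that direction (permutation p = 2e-05 against random occupied genes, the smallest the permutations can give). That value may equally reflect real IRF3 at open promoters, because an immunoprecipitation without antibody or from cells lacking IRF3 was not analysed here.

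Regions of replicate 1 alone lay at gene ends less often than those of replicate 2 alone. A difference in peak strength between the sets was argued against, since the Mantel-Haenszel odds ratio over 10 classes of −log10 q was 4.90 (95% interval 4.35 to 5.52). A tilt of the whole library of replicate 2 toward gene ends was a candidate explanation. Over shared regions the median log2 ratio of fold enrichment, replicate 2 over replicate 1, was 0.60 at gene ends and 0.10 over 10 kb away. The difference of 0.51 went in the direction of a tilt (permutation p = 1e-05, the smallest the permutations can give). It cannot decide the question, because strength was not matched and stronger shared regions lay at gene ends more often. The permuted regions also came from 1 pair of libraries and are not replicates. The design gives no biological difference between the replicates, so none was tested.

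Some of the broadest regions lay at plasma cell genes. Of the 71 shared regions longer than 5 kb, 10 touched 9 of the 35 plasma cell and myeloma list genes, namely ITGB7 (19.8 kb), TENT5C (19.4 kb and 7.74 kb), TXNDC5 (17.5 kb), XBP1 (12 kb), PRDM1 (10.9 kb), CCND2 (10.7 kb), MYC (7.87 kb), PIM2 (6.56 kb) and TNFRSF17 (5.47 kb). Whether these are only the strongest regions was tested against narrower regions of matched strength. Of 71 narrower regions matched in strength, 2 touched such genes (odds ratio 5.60, 95% interval 1.13 to 54.5, Fisher's exact p = 0.0308). The bound set for this test was an interval above 1. It did not allow for the list having been picked from 15 because the pattern was seen in it. The p of this test adjusted over the 15 lists was 0.463. With 5 matched regions per broad region, 3 of 355 touched such genes (odds ratio 19.02, 95% interval 4.72 to 110.6, Fisher's exact p = 1.76e-06). Among regions touching a coding gene the odds ratio was 17.43 (95% interval 4.31 to 101.7, Fisher's exact p = 3.74e-06). Neither of these larger comparisons was adjusted over the 15 lists. Long regions also covered the non-coding RNA genes NEAT1 (12.5 kb) and MALAT1 (11.9 kb), so recovery along heavily transcribed gene bodies stays open as a candidate explanation, and no biological explanation was tested.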
